A study of Drosophila melanogaster with 4 samples.

How the data were processed

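Gene expression was measured in testes and in seminal vesicles with the adjoining terminal epithelium of adult *Drosophila melanogaster* males, with 2 libraries per tissue and 4 in all. The count of reads per gene was deposited by the authors for each library as raw values, not normalised. Per the labels, the libraries were made with a stranded poly(A) kit and read from one end, and the processing notes list CASAVA 1.8.2, TopHat2 2.1.0 and HTSeq 0.6.1p1 without giving their settings. Reads were mapped by the authors to FlyBase release 6.06. External spike-in RNAs were added from a different pool in each tissue.

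Each file held 17409 gene rows, 96 spike-in rows and 5 summary rows for reads given to no gene. Spike-in and summary rows were left out of library sizes and tests. Of the gene identifiers, 17172 (98.6%) had a symbol and a position in a newer annotation of the same Release 6 assembly, and 237 had none. Gene counts per library were 14088989 and 15528462 for testis and 13385256 and 11120405 for seminal vesicle. A count of 0 allows a level of up to 0.213 and 0.193 CPM in the testis libraries and up to 0.224 and 0.27 CPM in the seminal vesicle libraries (3 counts of the total). Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

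The strand setting of the counting is not stated. It was checked on the counts: of 121 genes lying wholly inside exons of genes on the opposite strand, 77 had 10 or more counts, against 2 of 357 genes lying inside exons on the same strand, as strand-specific counting would leave them.

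Genes were filtered with filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), normalised with TMM, and tested with the robust quasi-likelihood F test, seminal vesicle against testis, in R 4.3.3. The adjusted p threshold was 0.05 (Benjamini-Hochberg). Changes over 2-fold were tested with edgeR glmTreat. The standard error of a log2 fold change is its size over the square root of F. Folds of genes with 0 counts in a tissue are lower bounds against 3 counts over both libraries, and genes with 1 to 3 counts are given a ratio of counts with a 95% counting interval.

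Before the data were examined, 29 gene lists with 768 entries were fixed, along with the tests, the alternatives and the rule for named genes. Entries were matched by symbol (747) or synonym (14), 7 were unmatched and 18 matched genes are not in the files. Lists and chromosome arms were tested with camera in limma 3.58.1 on log CPM (prior count 2), with a preset correlation of 0.01 and again with a correlation estimated from the data, and with fry. Fisher's exact test compared calls on the X and chromosome 4 with the major autosomes, and noncoding with protein-coding genes. Stage order was tested by a two-sided permutation of genes (100000 draws). Genes are not independent replicates in any of these tests.

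Named genes were chosen by rule. In each list these were the 2 members with the highest mean log CPM and up to 2 called members with the largest change against the list's median. Over all genes they were the 8 with the largest fold in each direction, among called genes with a mean of at least 50 CPM in the higher tissue, and the 5 most abundant in each tissue. The 3 most abundant restricted genes of each tissue, the Y-linked list, the roX RNAs, per, tim, Clk, cyc, cry, Abd-B, tj, vas, Mhc, SP and Dup99B complete the rule. Genes outside it are said to be chosen after their values were seen.

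Alternatives were DESeq2 size factors, library size only, spike-in factors, no filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out in turn, other detection limits, a threshold of 0.01 and thinned counts. A fit without mitochondrial and ribosomal RNA genes and the 2 most abundant seminal vesicle genes was added after the data were seen. The series text gives dissections on 2 days as the 2 replicates. That equal replicate numbers share a day is inferred from it, since the labels give no day per library, and the block rests on this. Over genes, the difference between replicates in testis correlated at 0.07 with that in seminal vesicle. The block gave 4834 genes higher in seminal vesicle and 5122 higher in testis. Values with the block stand beside a result only where they change its call.

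The steps were tested on simulated counts of 11737 genes, with 200 genes planted in each of 5 simulations. Each gene was drawn independently of the others. Apart from planted genes and lists, each gene had the same mean in both tissues, so most genes were unchanged. In the data 86.6% of tested genes were called. The simulation therefore does not show how scaling, the gene test or camera behave where most genes change. Of planted genes, 36.4% at 2-fold and 91.8% at 4-fold were recovered, and 0.15% of unchanged genes were called. Of 5 planted lists of 30 genes, camera called 5 with the preset correlation and 0 with an estimated one, and it called 0 of 100 lists with no planted change. With 2 libraries per tissue, no test of outlying libraries and no count over other splits of the samples was run. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.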

Results

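Poly(A) RNA was sequenced from testes and from seminal vesicles of adult *Drosophila melanogaster* males of the modENCODE Oregon-R strain, aged 4 to 5 days and kept under constant light. The seminal vesicle is the paired sac that stores mature sperm, and its dissected samples also held the terminal epithelium at the base of the testis. Each tissue was represented by 2 libraries, from dissections on 2 consecutive days, so each comparison set 2 testis libraries against 2 seminal vesicle libraries. The deposited gene counts summed to 14088989 and 15528462 in the testis libraries and to 13385256 and 11120405 in the seminal vesicle libraries. Levels below are TMM-normalised CPM, given as mean ± SD over the 2 libraries of a tissue. In a pair of levels testis comes first. Log2 fold changes are seminal vesicle minus testis with their standard error, so a positive value means higher in seminal vesicle. Adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The comparison addresses which genes distinguish the sperm-producing tissue from the sperm-storing tissue in males of the same strain and age. The labels do not pair the tissues by animal.

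Germline genes (sperm tail, spermatid, meiotic and Y-linked) were higher in testis, while genes of epithelium, muscle, basement membrane, secretion, immunity and the circadian clock were higher in seminal vesicle by camera with a preset correlation. None of these list calls was kept with an estimated correlation, where adjusted p ran from 0.384 to 0.54. Of 11737 genes tested, 4944 were higher in seminal vesicle and 5223 higher in testis, and 1570 were not called. Changes were large as well as many: 3930 genes were higher in seminal vesicle and 4305 higher in testis by over 2-fold with TMM scaling (edgeR glmTreat). These numbers were 3447 and 4765 with library size only and 2667 and 5063 with spike-in factors. Fitted changes passed 100-fold for 236 called genes in seminal vesicle and 340 in testis. The 2 testis libraries correlated at r = 0.993 over log CPM of genes and the 2 seminal vesicle libraries at r = 0.978, against 0.402 to 0.504 between tissues, where genes are not independent replicates. With scaling to the spike-in RNAs in place of the gene counts, the split moved to 3342 genes higher in seminal vesicle and 5922 genes higher in testis, and the median log2 fold change of all tested genes moved from -0.11 to -0.97. The spike-in pools differed between the tissues, so that scaling is confounded with tissue.

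A few transcripts dominated the seminal vesicle. CG18628 (FBgn0036091; 3L, 10639740 to 10640136, plus strand of the Release 6 assembly) took 15.1% and 15.6% of all gene counts in the 2 seminal vesicle libraries. Its level was 322 ± 54.6 against 175350 ± 15090 CPM (544-fold, log2 fold change 9.09 ± 0.42, adjusted p = 3.12e-05). Jhbp5, of the juvenile hormone binding protein family (FBgn0038395; 3R, 16044747 to 16046130, minus strand), followed with 459.8 ± 61.2 against 51211 ± 3846 CPM (111-fold, adjusted p = 3.4e-05). The metallothionein gene MtnA rose from 81 ± 6.81 to 16841 ± 2537 CPM, mfas from 87.7 ± 6.11 to 11260 ± 1702 CPM and CG5612 from 4.13 ± 0.978 to 9174 ± 903 CPM, and the largest adjusted p of these 3 was 3.33e-05. In testis the most abundant transcripts were the mitochondrial large ribosomal RNA mt:lrRNA and CG4836, followed by the sperm leucylaminopeptidases S-Lap1, S-Lap7 and loopin-1. The mt:lrRNA level was 13331 ± 4013 against 6536 ± 3997 CPM and did not pass the test (adjusted p = 0.105). It passed with the replicate block (0.0455), library size only (0.0374), spike-in factors (0.00848) and DESeq2 (0.0465). Without seminal vesicle replicate 1 its log2 fold change was -1.83 and without replicate 2 -0.52. Such fits leave 1 library in a tissue and take the spread from the other tissue. Calls gained or lost in them therefore say little about the spread of the reduced tissue. CG4836 (3R, 20013872 to 20018248, plus strand) stood at 12079 ± 1368 against 2523 ± 1641 CPM (log2 fold change -2.26 ± 0.52, adjusted p = 0.00751). The 10 most abundant genes took 26.9% and 25.7% of counts in seminal vesicle but 7.07% and 8.43% in testis. Testis had more genes at 1 CPM or above, 10543 and 10548 per library against 9595 and 9801. These CPM are on total gene counts, so the dominant seminal vesicle transcripts lower the CPM of its other genes. The numbers were not recomputed on effective library sizes.

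Among abundant genes the largest fold changes belonged mostly to uncharacterised genes. On the seminal vesicle side, the noncoding RNA lncRNA:CR43684 (FBgn0263767; 3L, 15062207 to 15062622, minus strand) rose from 1.42 ± 0.134 to 3738 ± 652 CPM (2613-fold, adjusted p = 3.12e-05). CG10175 rose from 0.859 ± 0.0217 to 1411 ± 808 CPM, and CG42237 from 0.149 ± 0.0454 to 244 ± 46.2 CPM (adjusted p = 5.74e-05 and 3.12e-05). CG42822, CG42828, CG14694 and DIP-zeta, of the Dpr-interacting immunoglobulin family, had 3 or fewer testis counts in all, against 2317 to 6295 in seminal vesicle. CG42822 (3R, 17413901 to 17414607, plus strand) had a count ratio of 3280 (counting interval 1120 to 15900), CG42828 a count ratio of 4330 (counting interval 777 to 171000), CG14694 a count ratio of 1480 (counting interval 505 to 7160) and DIP-zeta a count ratio of 1810 (counting interval 500 to 15000), seminal vesicle over testis. On the testis side, the mitofusin gene fzo, which acts in the fusion of spermatid mitochondria (FBgn0011596; 3R, 23201644 to 23204034, minus strand), stood at 211 ± 13.4 against 0.793 ± 0.545 CPM (276-fold, log2 fold change -8.11 ± 0.47, adjusted p = 4.5e-05). The adenylate cyclase gene ACXB (285-fold), the proteasome paralog Prosalpha4T1 (283-fold), CG33490 (368-fold), CG5681 (321-fold), CG7907 (307-fold) and lncRNA:CR32835 (250.2-fold) were all higher in testis, and CG42830 had 3 seminal vesicle counts against 1716 in testis, a count ratio of 366 (counting interval 125 to 1780).

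Tissue-restricted genes numbered 388 for testis and 117 for seminal vesicle. These were at 1 CPM or above, on total gene counts, in both libraries of one tissue and under 0.1 CPM in both of the other. The testis set held 210 noncoding RNA genes and 164 protein-coding genes, and the seminal vesicle set held 19 and 97. The most abundant in testis were Prosalpha3T (3R, 31122527 to 31123415, minus strand; 37.3 ± 1.17 against 0.0408 ± 0.0577 CPM), CG5250 (34.6 ± 0.396 CPM in testis) and CG34230 (24 ± 0.23 CPM in testis). In seminal vesicle they were CG42828 (3R, 23373703 to 23374245, plus strand; 122 ± 72 CPM), CG13460 (3L, 15061029 to 15061705, minus strand; 45.8 ± 1.75 CPM) and CG14245 (3R, 26728727 to 26729341, plus strand; 26.5 ± 5.59 CPM). CG14245 had 0 counts in both testis libraries, which makes it at least 292-fold higher against a floor of 3 counts over both. The numbers depended on the threshold and on single libraries. They were 227 and 66 from 2 CPM up, and 153 and 47 with 0 counts in the other tissue, while effective library sizes gave 199 and 131. Testis had 726 restricted genes without seminal vesicle replicate 2, and seminal vesicle had 180 without testis replicate 1 and 215 without testis replicate 2.

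All 9 lists of male germline genes, fixed before the data were examined, were higher in testis by camera with a preset correlation, and none kept its call with an estimated correlation. Of 27 early germline genes tested, 23 were higher in testis and 3 higher in seminal vesicle with the same numbers adjusted over the list alone, at a median of 7.3-fold higher in testis. For the early germline list, camera gave adjusted p = 0.000815 and adjusted p = 0.408 with an estimated correlation. The germline helicase gene vas fell from 17.1 ± 5.1 to 1.3 ± 0.93 CPM and the Tudor-domain gene papi from 193 ± 2.45 to 71.3 ± 21.9 CPM (adjusted p = 0.000591 and 0.0039). Of the exon bases of vas, 24.6% overlap another gene on the same strand. The members going the other way were tud (143 ± 5.58 against 333 ± 82.3 CPM), dnd (0.652 ± 0.0154 against 8.54 ± 0.723 CPM) and ovo (0.89 ± 0.105 and 2.18 ± 0.549 CPM). The tud call was lost with spike-in scaling and the ovo call in 6 alternatives. Of 14 meiotic arrest regulators, which switch on the transcription program of spermatocytes, 13 were higher in testis and 1 higher in seminal vesicle, also adjusted over the list alone, at a median of 56.3-fold higher in testis. For the meiotic arrest regulators list, camera gave adjusted p = 0.000815 and adjusted p = 0.437 with an estimated correlation. Examples were achi (58.5 ± 5.53 against 7.04 ± 0.496 CPM) and mip40 (5.69-fold higher in testis), and the exception was the RNA export gene Nxt1 (1.75 ± 0.252 against 6.89 ± 2.02 CPM).

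Of 21 spermatocyte and meiosis genes, 19 were higher in testis and 1 higher in seminal vesicle, also adjusted over the list alone, at a median of 24-fold higher in testis. For the spermatocyte and meiosis list, camera gave adjusted p = 9.78e-05 and adjusted p = 0.44 with an estimated correlation. The testis tubulin gene betaTub85D (FBgn0003889; 3R, 9408383 to 9410282, minus strand) stood at 3114 ± 190 against 105 ± 62 CPM (log2 fold change -4.89 ± 0.54, adjusted p = 0.000346), and fest was 7.79-fold higher in testis. The exception, the cohesin gene SMC1, had log2 fold change 0.54 ± 0.19 with adjusted p = 0.036 and 0.0551 with the replicate block. The SMC1 call was also lost with library size only (adjusted p = 0.51), no filter (0.0628) and DESeq2 (0.161). Of 42 spermatid differentiation genes, 40 were higher in testis and 1, Dark, higher in seminal vesicle, also adjusted over the list alone, at a median of 6.13-fold higher in testis. For the spermatid differentiation list, camera gave adjusted p = 4.01e-06 and adjusted p = 0.54 with an estimated correlation. S-Lap1 (3L, 8617235 to 8619474, plus strand) stood at 8849 ± 2114 against 1198 ± 632 CPM and S-Lap7 at 6631 ± 1242 against 949 ± 505 CPM (adjusted p = 0.00193 and 0.00199). Dark (20 ± 0.89 and 30.6 ± 4.74 CPM) shares 56.9% of its exon length with exons on the other strand, and its call was lost under 4 alternatives and turned negative with spike-in scaling, as did the direction of SMC1. All 15 cup and comet genes, transcribed after meiosis, were higher in testis, also adjusted over the list alone, at a median of 16.9-fold higher in testis. For the cup and comet transcripts list, camera gave adjusted p = 0.000501 and adjusted p = 0.531 with an estimated correlation. In this list w-cup fell from 2753 ± 222 to 183 ± 116 CPM and schuy from 562 ± 16.1 to 104 ± 74.1 CPM (adjusted p = 0.000902 and 0.00672).

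Of 29 axonemal dynein and flagellum genes, 28 were higher in testis over all genes tested, and adjusted over the list alone the remaining gene, Sdic2, named after its value was seen, was called higher in seminal vesicle. The median was 24-fold higher in testis. For the axonemal dynein and flagellum list, camera gave adjusted p = 4.27e-06 and adjusted p = 0.519 with an estimated correlation. The tubulin glycylase gene TTLL3B (789 ± 40.5 against 161 ± 103 CPM) and the ciliary gene Bug22 (256 ± 10.2 against 71.4 ± 27 CPM) had the highest mean log CPM over the 4 libraries (adjusted p = 0.00588 and 0.00259). All 22 testis-type mitochondrial paralogs, among them the spermatid cytochrome c gene Cyt-c-d (6.31-fold) and ttm2 (9.22-fold), were higher in testis, also adjusted over the list alone, at a median of 23.5-fold higher in testis. For the testis-type mitochondrial paralogs list, camera gave adjusted p = 2.79e-05 and adjusted p = 0.519 with an estimated correlation.

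Germline transcripts remained countable in both seminal vesicle libraries. The spermatid differentiation list took 6.37% and 7.16% of gene counts in testis, 0.487% in seminal vesicle replicate 1 and 0.978% in seminal vesicle replicate 2. Its members stood at a median of 10.2% and 22.3% of their testis level in the 2 seminal vesicle libraries, against 2.75% and 3.46% for spermatocyte and meiosis genes and 0.864% and 3.28% for meiotic arrest regulators. Early germline genes stood at 13.1% and 13.3%, above spermatid genes in replicate 1 and below them in replicate 2. The same medians were 3.68% and 9.02% for cup and comet genes, 2.63% and 5.74% for axonemal genes, and 3.14% and 5.97% for the mitochondrial paralogs. Without seminal vesicle replicate 2 the median excess in testis moved to 117-fold for meiotic arrest regulators, 36.1-fold for spermatocyte, 9.84-fold for spermatid, 27.3-fold for cup and comet and 38.2-fold for axonemal genes. Without seminal vesicle replicate 1 it was 29.9-fold for meiotic arrest regulators and 10.9-fold for cup and comet genes. Of the named genes, 31 moved by over 1.5 times in fold without seminal vesicle replicate 2 and 25 without replicate 1. Outside the Y, the moves included Prosalpha3T, Prosalpha4T1, CG34230, CG42830, CG5681, CG4836, fzo, fest, TTLL3B, ttm2, schuy, w-cup, S-Lap1, S-Lap7, betaTub85D, Cyt-c-d and loopin-1. They also included CG10175, CG42828, Clk, Acp36DE, mt:lrRNA, grh, upd1, shd, Gad1, Rdl, Dup99B, vas, Est-6 and Rab32. Without either testis library 3 moved, DIP-zeta, CG42828 and CG13460. The mean log2 fold change of cup and comet genes minus that of spermatid genes was -1.03 (two-sided permutation test over genes with 100000 draws, p = 0.014, Benjamini-Hochberg adjusted over 2 tests 0.028). For spermatid minus early germline genes the difference was -0.55 (permutation p = 0.21), and it was 0.16 without seminal vesicle replicate 1 and -1.24 without seminal vesicle replicate 2 (adjusted permutation p = 0.738 and 0.00931).

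**Figure D1:**
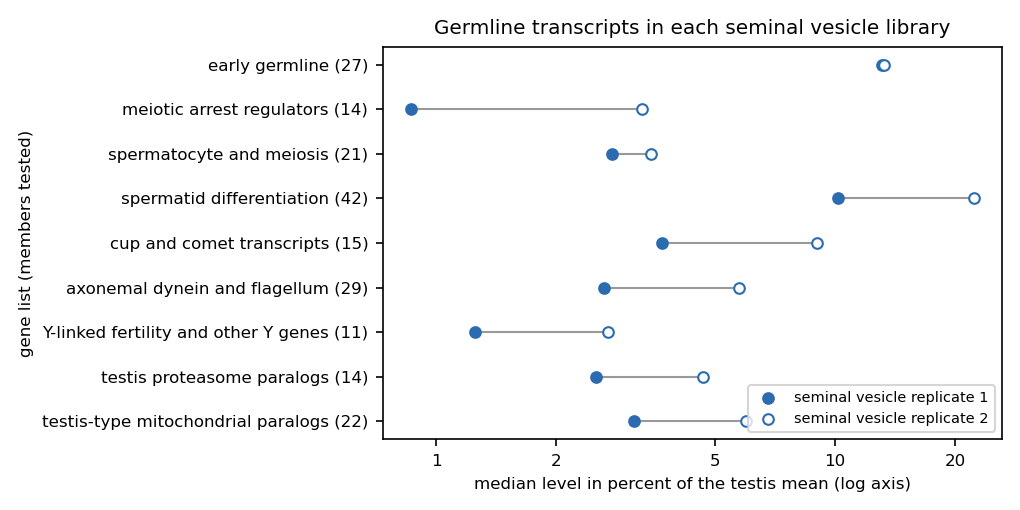
For each germline gene list (vertical axis, members tested in brackets), the points give the median level of its members in each seminal vesicle library as a percent of their mean testis level (horizontal log axis). The spermatid list stands at 10.2% and 22.3%, the Y-linked list at 1.25% and 2.70%.

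The Y was the only chromosome with every tested gene higher in testis. All 16 Y-linked genes tested were higher in testis (camera over chromosome arms adjusted p = 0.000265; adjusted p = 0.929 with an estimated correlation). The list of 11 tested Y genes with known names had a median 51.7-fold higher in testis, and all 11 were called, also adjusted over the list alone. For the Y-linked fertility and other Y genes list, camera gave adjusted p = 0.000449 and adjusted p = 0.519 with an estimated correlation. Those with the highest mean log CPM over the 4 libraries were CCY (Y, 3649996 to 3666928, plus strand; 117 ± 18.1 against 4.86 ± 3.88 CPM) and ARY (56.3 ± 11 against 3.43 ± 2.42 CPM). The dynein heavy chain genes kl-2, kl-3 and kl-5 of the sperm tail were higher in testis by 201-fold, 51.7-fold and 61.2-fold, WDY by 121-fold, ORY by 116-fold, Ppr-Y by 44.3-fold, PRY by 40.8-fold and Pp1-Y2 by 24.2-fold. FDY had 3 seminal vesicle counts against 431 in testis, a count ratio of 92 (counting interval 31.3 to 448), and Pp1-Y1 had 0 counts in all 4 libraries. Without seminal vesicle replicate 2 the list median was 78.9-fold, and that of all Y-linked genes 55.4-fold, or 20.2-fold without replicate 1. The median log2 fold change of all Y-linked genes was -5.149 in the main fit, -3.18 with no filter (9.06-fold) and -4.404 with DESeq2 (21.2-fold). Single folds moved more: the log2 fold change without seminal vesicle replicate 1 and without replicate 2 was -5.69 and -11.45 for ORY, -6.15 and -8.05 for WDY and -4.85 and -6.23 for Ppr-Y. It was -3.93 and -5.79 for CCY, -3.44 and -5.04 for ARY and -5.265 and -10.62 for FDY. For kl-3 it moved from -5.69 to -6.30 without replicate 2. All of these stayed higher in testis.

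X-linked and chromosome 4 genes leaned the other way. On the X, 918 of 1819 tested genes were higher in seminal vesicle and 679 higher in testis, against 3872 and 4455 on the 4 major autosome arms (odds ratio 1.56, 95% interval 1.39 to 1.74, Fisher's exact test p = 9.92e-16). The median log2 fold change was 0.63 on the X, but camera did not call the arm (adjusted p = 0.107), and with spike-in scaling the X median fell to -0.23 while the odds ratio was 1.53. Of 88 genes on chromosome 4, 57 were higher in seminal vesicle and 19 higher in testis (odds ratio 3.45, 95% interval 2.02 to 6.15, Fisher's exact test p = 6.63e-07; camera adjusted p = 0.00123; adjusted p = 0.929 with an estimated correlation). Genes are not independent replicates in these Fisher tests. The camera adjusted p was 0.271 for arm 2L, 0.773 for 2R, 0.605 for 3L and 0.79 for 3R. For 2R the median was 0.04 and the mean -0.03.

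**Figure D2:**
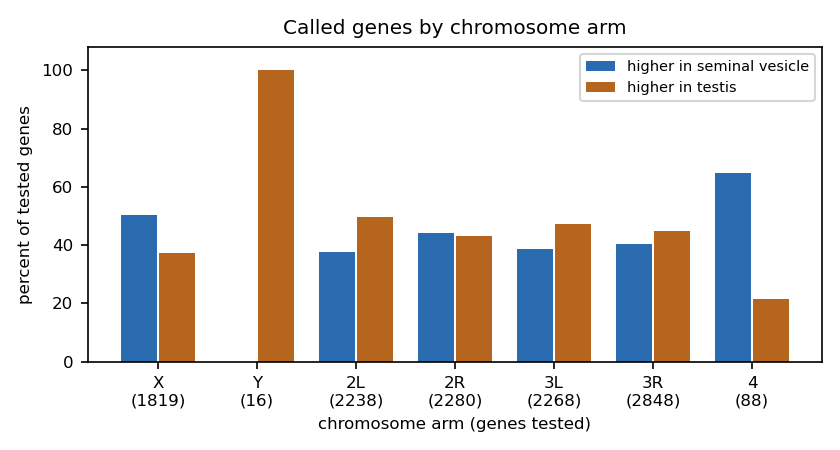
Bars give the percent of tested genes on each chromosome arm (genes tested in brackets) called higher in seminal vesicle (blue) or in testis (brown) by edgeR. On the X 50.5% were higher in seminal vesicle and 37.3% in testis, and on the Y 100% were higher in testis.

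The noncoding RNAs of dosage compensation, which in males targets the X chromosome, were both higher in seminal vesicle. The lncRNA:roX1 level (X, 3857230 to 3862697, minus strand) was 6.23 ± 1.91 against 145 ± 1.4 CPM (23.2-fold, log2 fold change 4.53 ± 0.29, adjusted p = 5.27e-05). The lncRNA:roX2 level was 0.652 ± 0.0154 against 7.65 ± 2.79 CPM (11.7-fold, adjusted p = 0.000332). Of 8 dosage compensation genes tested, roX RNAs included, 4 were higher in seminal vesicle and 3 higher in testis, also adjusted over the list alone (camera adjusted p = 0.778, and adjusted p = 0.817 with an estimated correlation). Those in seminal vesicle were the roX RNAs and, named after their values were seen, msl-1 and msl-2. The acetyltransferase gene mof (13.8 ± 0.954 against 8.89 ± 0.00128 CPM), msl-3 (22.2 ± 3.46 against 10.2 ± 0.0604 CPM) and the helicase gene mle (log2 fold change -0.52 ± 0.18, adjusted p = 0.0337, 0.0829 with the replicate block) were the members higher in testis. Each call was lost without testis replicate 1, and those of mof and mle also without testis replicate 2. Clamp did not pass the test at 65.8 ± 1.26 against 50 ± 2.22 CPM (adjusted p = 0.0739), but did so with library size only or spike-in factors. Its log2 fold change was -0.43 without seminal vesicle replicate 1 and -0.36 without replicate 2. Tested noncoding RNA genes were mostly higher in testis. Of 2442 in the files, 1060 passed the filter, which a gene could pass through 1 tissue alone. Of these 1060, 889 were higher in testis and 134 higher in seminal vesicle. Among called genes, 86.9% of noncoding and 47.4% of protein-coding genes were higher in testis (odds ratio for seminal vesicle 0.136, 95% interval 0.112 to 0.164, Fisher's exact test p = 2.24e-140).

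The proteasome split by paralog. All 14 testis proteasome paralogs were higher in testis, also adjusted over the list alone, at a median of 28.6-fold higher in testis. For the testis proteasome paralogs list, camera gave adjusted p = 3.94e-05 and adjusted p = 0.408 with an estimated correlation. The abundant members were Prosalpha6T (197 ± 17.7 against 7.2 ± 1.64 CPM) and Rpt6R (203 ± 12.8 against 8.9 ± 3.47 CPM), and Prosalpha3T was among the testis-restricted genes. The members stood at a median of 2.51% and 4.67% of their testis level in the 2 seminal vesicle libraries. The 31 somatic proteasome subunits had no common direction, with 11 higher in each tissue over all genes tested, 10 in seminal vesicle and 7 in testis with the replicate block, and 10 and 9 adjusted over the list alone (camera adjusted p = 0.936, and adjusted p = 0.998 with an estimated correlation). Their median log2 fold change was -0.25 while the mean and the camera direction were positive. Rpt3 rose 10.9-fold in seminal vesicle (14.3 ± 1.64 against 156 ± 10.7 CPM) and Rpn12 rose 6.01-fold (adjusted p = 5.41e-05 and 8.12e-05). Rpn2 was at 279 ± 9.81 against 213 ± 2.47 CPM (adjusted p = 0.166), a call gained with library size only or spike-in factors. Its log2 fold change was -0.39 without either seminal vesicle library. Rpn6 was lower in seminal vesicle with adjusted p = 0.0492 and 0.0904 with the replicate block.

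The vacuolar ATPase, a proton pump of many subunits, also had members in both directions. Of 28 genes tested, 13 were higher in seminal vesicle and 15 higher in testis, also adjusted over the list alone (camera adjusted p = 0.996, and adjusted p = 0.999 with an estimated correlation). The median log2 fold change was -1.70, whereas the camera direction was positive and fry called a positive balance (adjusted p = 0.0221). With a filter of 5 CPM the median turned to 3.15-fold higher in seminal vesicle. Members higher in seminal vesicle included Vha16-1 (144 ± 21.5 against 2299 ± 170 CPM), Vha68-2 (53 ± 2.25 against 1247 ± 118 CPM), Vha55 (272 ± 15.1 against 1033 ± 101 CPM) and Vha100-2 (29-fold higher), with adjusted p between 3.95e-05 and 0.000843. The Vha55 call was lost with spike-in scaling. Paralogs of the same subunits went the other way, for example Vha100-3 (205 ± 22.3 against 3.98 ± 2.4 CPM), Vha16-2 (21 ± 2.06 against 0.403 ± 0.339 CPM) and Vha68-3 (601 ± 122 against 61.8 ± 32.7 CPM), examples chosen after their values were seen. The list as a whole took 0.257% and 0.263% of counts in testis and 0.742% and 0.747% in seminal vesicle.

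**Figure D3:**
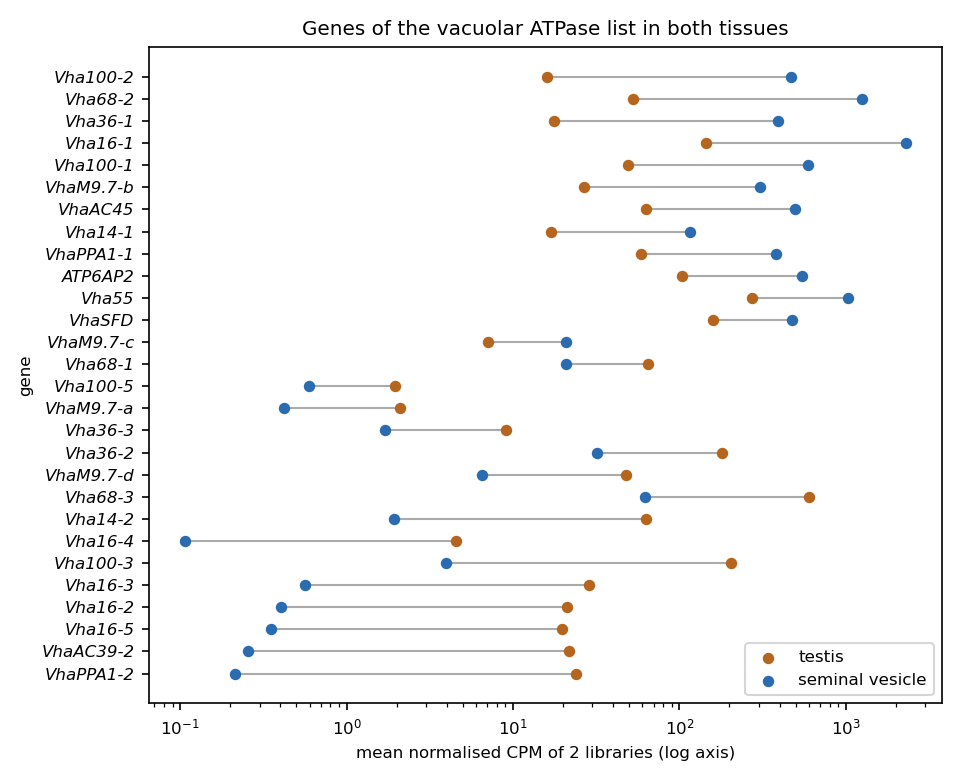
Mean normalised CPM (horizontal log axis) of each tested gene of the vacuolar ATPase list in testis (brown) and seminal vesicle (blue), ordered by log2 fold change, each point the mean of 2 libraries. In 13 genes the seminal vesicle point lies to the right, up to Vha16-1 at 2299 CPM, and in 15 genes the testis point does.

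Epithelial, basement membrane and muscle genes were higher in seminal vesicle. Of 37 epithelial polarity and junction genes, 35 were higher in seminal vesicle and 1 higher in testis, also adjusted over the list alone, at a median of 8.79-fold higher in seminal vesicle. For the epithelial polarity and junctions list, camera gave adjusted p = 4.27e-07 and adjusted p = 0.423 with an estimated correlation. The sodium pump gene Atpalpha rose from 125 ± 10.7 to 1034 ± 87.5 CPM (adjusted p = 0.000156), and its beta subunit gene nrv2 fell from 529 ± 8.85 to 179.5 ± 5.2 CPM (adjusted p = 0.00146). Of 22 basement membrane and integrin genes, 21 were higher in seminal vesicle, 22 adjusted over the list alone (wb added, named after its value was seen), and none higher in testis, at a median of 17-fold higher in seminal vesicle. For the basement membrane and integrins list, camera gave adjusted p = 3.44e-06 and adjusted p = 0.384 with an estimated correlation. The integrin gene mys rose 18.5-fold to 487 ± 50.8 CPM and the talin gene rhea 4.38-fold to 499.5 ± 102 CPM. Of 27 muscle genes, 24 were higher in seminal vesicle and 1 higher in testis, also adjusted over the list alone, at a median of 31.2-fold higher in seminal vesicle. For the muscle list, camera gave adjusted p = 1.56e-06 and adjusted p = 0.384 with an estimated correlation. The myosin heavy chain gene Mhc (2L, 16766566 to 16788766, plus strand) stood at 18.4 ± 0.642 against 754 ± 129 CPM (log2 fold change 5.36 ± 0.32, adjusted p = 4.22e-05). The list took 0.166% and 0.186% of counts in testis and 0.736% and 0.582% in seminal vesicle. Among its abundant members, Act87E did not differ by the test (559.6 ± 33.6 against 463 ± 54.5 CPM, adjusted p = 0.358). Its log2 fold change was -0.41 without seminal vesicle replicate 2. Msp300 was higher in testis (696 ± 143 against 351 ± 145 CPM, adjusted p = 0.0499), a call lost without either testis library. Of 13 tracheal and cuticle genes, 11 were higher in seminal vesicle and 1, grh, higher in testis, also adjusted over the list alone (camera adjusted p = 0.00631; adjusted p = 0.384 with an estimated correlation). The chitin synthase gene kkv was at 7.73 ± 0.866 against 158 ± 20.6 CPM and ttk at 29.2 ± 1.03 against 116 ± 5.71 CPM.

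**Figure D4:**
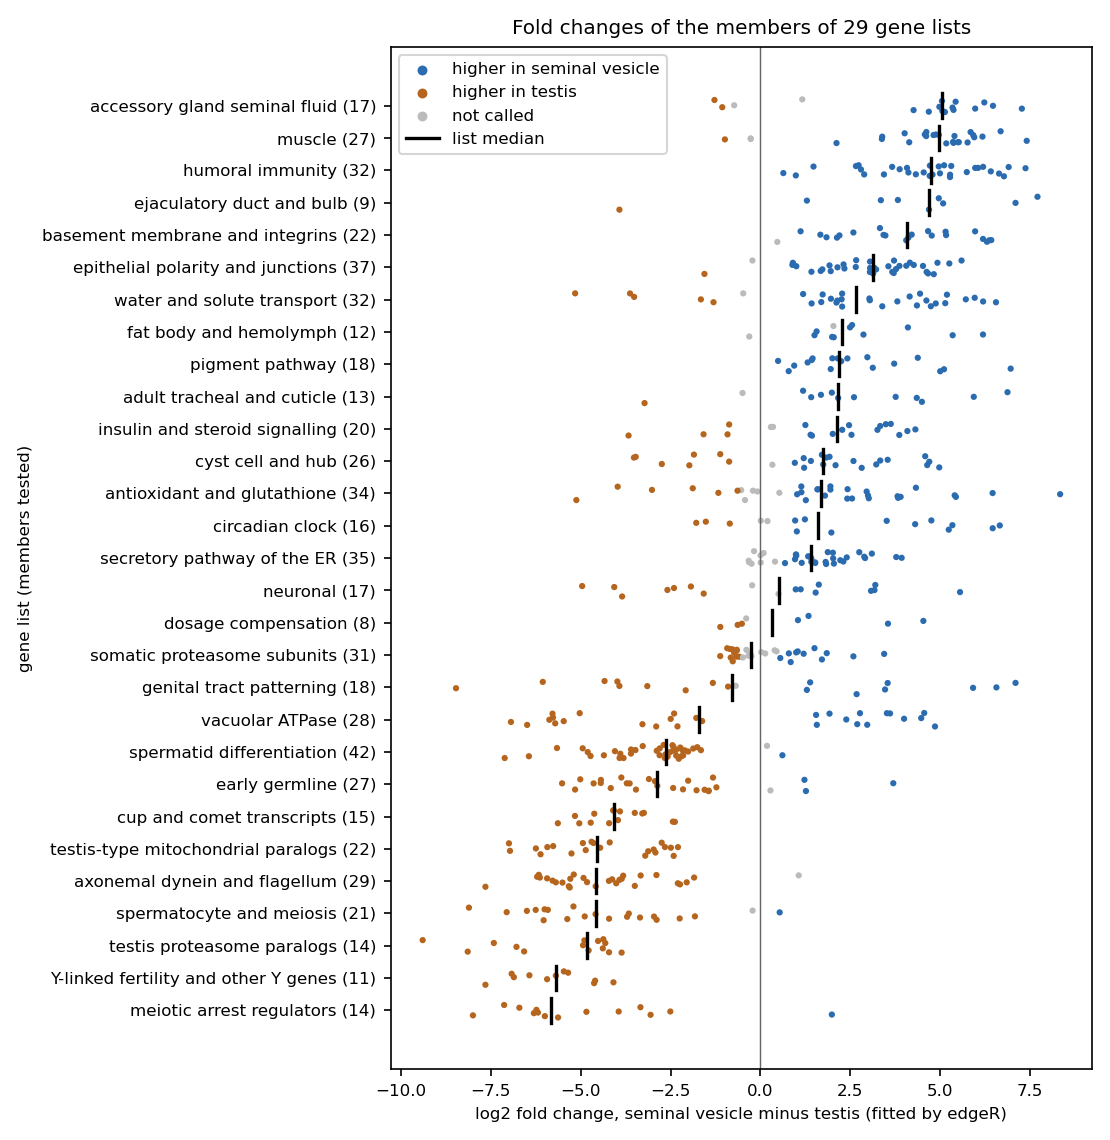
Each point is a tested gene, placed by its log2 fold change (horizontal axis, seminal vesicle minus testis, fitted by edgeR) in its gene list (vertical axis), and the black line is the list median. Medians run from -5.81 for meiotic arrest regulators to 5.06 for accessory gland genes, and points within 1 list vary by several log2 units.

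Most tested genes of protein secretion and of the ducts and glands downstream of the testis were higher in seminal vesicle. Of 35 genes of the endoplasmic reticulum secretory pathway, 27 were higher in seminal vesicle, none higher in testis, also adjusted over the list alone, at a median of 2.67-fold higher in seminal vesicle. For the secretory pathway of the ER list, camera gave adjusted p = 0.000143 and adjusted p = 0.437 with an estimated correlation. The chaperone gene Hsc70-3 rose from 248 ± 20 to 1159 ± 158 CPM and ERp60 from 473 ± 14.3 to 1049 ± 84.8 CPM, the latter a call lost with spike-in scaling and without testis replicate 1. Of 9 genes of the ejaculatory duct and bulb, 8 (7 with the replicate block) were higher in seminal vesicle and 1, prd, higher in testis, also adjusted over the list alone (camera adjusted p = 0.0173; adjusted p = 0.408 with an estimated correlation). EbpIII was at 29.9 ± 1.42 against 1015 ± 62.1 CPM and Est-6 at 9.96 ± 0.0669 against 257 ± 126 CPM. Without seminal vesicle replicate 1 the median of this list was 17-fold. Of 52 accessory gland seminal fluid genes in the files, 17 passed the filter. Their median levels in the 2 testis libraries were 0.121 and 0.0583 CPM, so most passed through their seminal vesicle counts. Of the 17, 13 were higher in seminal vesicle (14 adjusted over the list alone) and 2 higher in testis. The median was 33.4-fold higher in seminal vesicle (camera adjusted p = 0.0118; adjusted p = 0.531 with an estimated correlation), but their levels were low. The median log2 fold change was 5.06, and 5.05 with SP at its bound. The most abundant, Acp36DE, was at 7.57 ± 1.39 against 16.8 ± 10.7 CPM (adjusted p = 0.0519; 0.00467 with the replicate block). Its log2 fold change was 1.67 without seminal vesicle replicate 2 and 0.30 without replicate 1. The whole list took 0.0108% of counts in seminal vesicle replicate 1 and 0.00467% in replicate 2, with a median log2 ratio of replicate 2 over 1 of -1.11. The sex peptide gene SP had 0 counts in testis and 1.39 ± 0.00397 CPM in seminal vesicle, at least 15.6-fold higher against a floor of 3 counts over both testis libraries. Dup99B stood at 0.297 ± 0.0908 against 9.3 ± 8.76 CPM (adjusted p = 0.00371). The members higher in testis, Sfp26Ad (2.81 ± 0.227 and 1.15 ± 0.108 CPM) and Acp95EF, lost their calls without either testis library, and all exon bases of Acp95EF overlap exons on the other strand. The list call was lost without seminal vesicle replicate 1 (adjusted p = 0.105), with DESeq2 statistics (0.12) and with a filter of 5 CPM (0.758). The list median was then 14.7-fold without seminal vesicle replicate 1 and 2.47-fold with the filter, and 12.6-fold with no filter.

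The Hox gene Abd-B (FBgn0000015; 3R, 16927212 to 16972236, minus strand) rose from 0.475 ± 0.095 to 66.2 ± 3.71 CPM (137-fold, log2 fold change 7.10 ± 0.25, adjusted p = 3.12e-05). The Hox gene abd-A rose from 21.1 ± 0.72 to 233 ± 0.361 CPM, the homeobox gene Lim1 from 3.35 ± 0.131 to 318 ± 29.6 CPM and exd from 15.8 ± 3.81 to 101 ± 8.94 CPM. Over the list of 18 genital tract patterning genes, 8 (7 with the replicate block) were higher in seminal vesicle and 9 higher in testis, also adjusted over the list alone (camera adjusted p = 0.9, and adjusted p = 0.943 with an estimated correlation). Its median log2 fold change was negative at -0.79, while fry called a positive balance (adjusted p = 0.00789) and the median log2 fold change turned to 1.49 with a filter of 5 CPM. Of 26 cyst cell and hub genes, markers of the somatic cells of the testis, 18 were higher in seminal vesicle and 7 higher in testis, also adjusted over the list alone, at a median of 3.31-fold higher in seminal vesicle. For the cyst cell and hub list, camera gave adjusted p = 0.0173 and adjusted p = 0.44 with an estimated correlation. The most abundant, Fas3 (18.8 ± 0.694 against 488 ± 31.4 CPM) and Stat92E (53 ± 5.1 against 188 ± 20.5 CPM), also act outside the testis, and the Stat92E call was lost with spike-in scaling. The hub ligand gene upd1 (19.7 ± 2.76 against 1.81 ± 1.53 CPM), the transcription factor genes chinmo (132 ± 10.1 against 12 ± 5.44 CPM) and tj (log2 fold change -1.12 ± 0.32, adjusted p = 0.016, not called without either testis library) were higher in testis.

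Most circadian clock genes were higher in seminal vesicle in these flies kept under constant light, while Clk was higher in testis. The feedback genes tim (FBgn0014396; 2L, 3493986 to 3508119, minus strand) and per (X, 2685580 to 2692780, plus strand) rose from 2.31 ± 0.113 to 235 ± 22.4 CPM and from 1.43 ± 0.285 to 54.2 ± 10.4 CPM (101-fold and 37.8-fold; log2 fold change 6.66 ± 0.29, adjusted p = 3.12e-05 for tim). The photoreceptor gene cry rose 40.5-fold (2.13 ± 0.369 against 86.7 ± 16.7 CPM) and cyc, which encodes a partner of Clk, 3.93-fold (10.3 ± 0.385 against 40.6 ± 0.804 CPM). Clk itself was at 160.1 ± 17.7 against 55.9 ± 32.1 CPM (log2 fold change -1.52 ± 0.43, adjusted p = 0.0166), a call lost without testis replicate 2 (adjusted p = 0.0674). Its log2 fold change was -2.27 without seminal vesicle replicate 2. The clock genes vri (2.94 ± 0.195 against 259.7 ± 20.2 CPM) and Pdp1 (8.16 ± 0.737 against 221 ± 24.9 CPM), chosen after their values were seen, were also higher in seminal vesicle. Of 16 clock genes tested, 11 were higher in seminal vesicle and 3 higher in testis, also adjusted over the list alone, at a median of 3.04-fold higher in seminal vesicle. For the circadian clock list, camera gave adjusted p = 0.0173 and adjusted p = 0.443 with an estimated correlation. The others higher in testis were Usp8 (3.45-fold) and slmb (1.8-fold, a call lost without either testis library). The most abundant member, the kinase gene sgg, was at 133 ± 11.9 against 313 ± 71.1 CPM (adjusted p = 0.00636, a call lost with spike-in scaling).

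**Figure D5:**
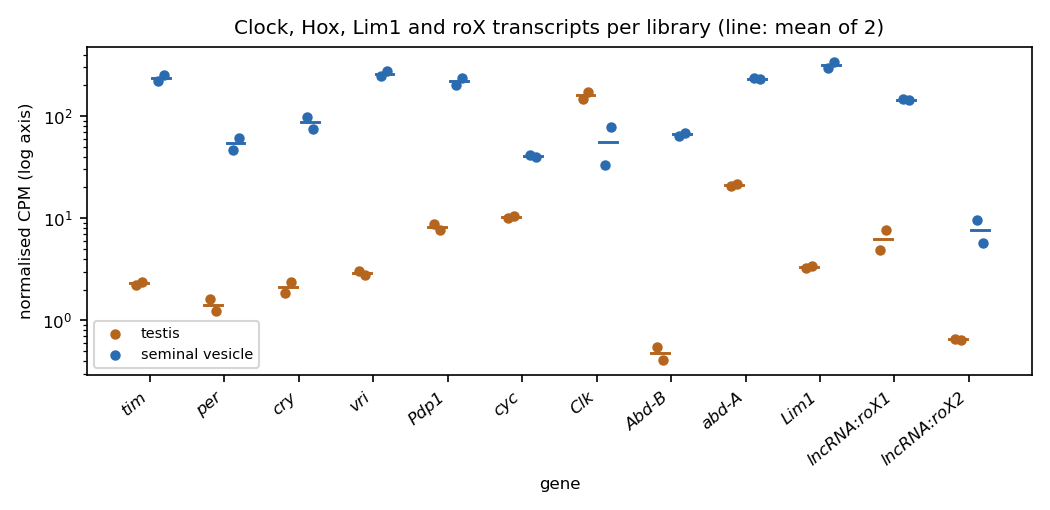
Normalised CPM per library (vertical log axis) of clock, Hox, Lim1 and roX genes, with 2 points per tissue and a line at their mean, testis in brown and seminal vesicle in blue. Of the genes drawn, only Clk has a higher mean in testis, at 160.1 against 55.9 CPM, and tim stands at 2.31 against 234.6 CPM.

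Humoral immunity genes were uniformly higher in seminal vesicle: all 32 tested were called in that direction, also adjusted over the list alone, at a median of 26.9-fold higher in seminal vesicle. For the humoral immunity list, camera gave adjusted p = 6.64e-07 and adjusted p = 0.384 with an estimated correlation. The median was 17.2-fold without seminal vesicle replicate 1. Beside it, the fat body and hemolymph list rose from 0.0262% and 0.0268% of counts in testis to 0.29% and 0.429% in seminal vesicle. Most of the seminal vesicle share came from the transferrin gene Tsf1, whose levels are given below. The NF-kappaB gene Rel rose from 9.53 ± 0.781 to 191 ± 39.5 CPM and the inhibitor gene cact 6.31-fold (adjusted p = 5.03e-05 and 0.000133). Of 34 antioxidant and glutathione genes, 23 were higher in seminal vesicle and 6 higher in testis, also adjusted over the list alone. For the antioxidant and glutathione list, camera gave adjusted p = 0.00779 and adjusted p = 0.384 with an estimated correlation. GstD1 rose 43.4-fold to 5750.1 ± 329.6 CPM (adjusted p = 4.12e-05). GstO1 fell from 77.9 ± 5 to 5.05 ± 2.41 CPM, and the thioredoxin gene dhd had 3 seminal vesicle counts against 173 in testis (a count ratio of 36.9 (counting interval 12.4 to 181)). GstS1 was at 1605 ± 2.46 against 713 ± 198 CPM (adjusted p = 0.0123, a call lost without either testis library). Of 32 water and solute transport genes, 26 were higher in seminal vesicle and 5 higher in testis, also adjusted over the list alone, at a median of 6.29-fold higher in seminal vesicle. For the water and solute transport list, camera gave adjusted p = 0.000355 and adjusted p = 0.408 with an estimated correlation. The citrate carrier gene Indy rose 20.4-fold (51.9 ± 8.64 against 1061 ± 280.3 CPM). Oatp30B did not pass the test (411 ± 27.9 against 295 ± 82 CPM, adjusted p = 0.175), but was called with library size only or spike-in factors. Its log2 fold change was -0.80 without seminal vesicle replicate 2. Eglp1 and ZnT35C were higher in testis by 35.6-fold and 12.4-fold. The others higher in testis, named after their values were seen, were bib, Nha1 and foi.

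All 18 pigment pathway genes (17 with the replicate block) were higher in seminal vesicle, also adjusted over the list alone, at a median of 4.59-fold higher in seminal vesicle (camera adjusted p = 0.000278; adjusted p = 0.384 with an estimated correlation). Among them were Rab32 (40.6 ± 3.03 against 355 ± 180 CPM) and cl (110.0 ± 0.218 against 273 ± 0.264 CPM, a call lost with spike-in scaling). Of 26 fat body and hemolymph genes in the files, 12 passed the filter. Of these 12, 10 were higher in seminal vesicle and none higher in testis, also adjusted over the list alone. For this list, camera gave adjusted p = 0.00591 and adjusted p = 0.384 with an estimated correlation. The transferrin gene Tsf1 was at 75 ± 8.54 against 3056 ± 1234 CPM and the fatty acid synthase gene FASN1 at 58.7 ± 2.22 against 428 ± 144 CPM. Of 20 insulin and steroid signalling genes, 14 were higher in seminal vesicle and 4 higher in testis, also adjusted over the list alone. For the insulin and steroid signalling list, camera gave adjusted p = 0.0118 and adjusted p = 0.519 with an estimated correlation. ImpL2 rose 10.1-fold (12.1 ± 1.46 against 122 ± 12.5 CPM). Akt did not pass the test (log2 fold change 0.35 ± 0.21, adjusted p = 0.167), but was called with a filter of 5 CPM (0.0452). Its log2 fold change was 0.51 without seminal vesicle replicate 1 and negative under library-size and spike-in scaling. The ecdysone synthesis genes shd and sad were higher in testis (9.65 ± 1.45 against 0.793 ± 0.545 CPM for shd, 1.54 ± 0.383 and 0.5 ± 0.101 CPM for sad, whose call was lost in 3 alternatives). The 17 neuronal genes had no common direction, with 8 higher in seminal vesicle and 7 higher in testis, also adjusted over the list alone (camera adjusted p = 0.9, and adjusted p = 0.971 with an estimated correlation). Their median log2 fold change was 0.50 and their mean negative, and the median was also negative with spike-in factors, no filter and DESeq2 and without seminal vesicle replicate 1. Syx1A (13.7 ± 2.59 against 116 ± 30.1 CPM) and unc-13 (18.4 ± 0.518 against 53.6 ± 13.3 CPM, a call lost with spike-in scaling) were higher in seminal vesicle. In contrast, Gad1 and Rdl had 2 and 1 seminal vesicle counts against 57 and 58 in testis (a count ratio of 18.2 (counting interval 4.82 to 154) and a count ratio of 37.1 (counting interval 6.4 to 1490)).

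With 2 libraries per tissue, the smallest p an exact permutation test of 1 gene could give is 0.333, and all adjusted p-values rest on the spread that edgeR pools over genes. The replicates were separate dissections on consecutive days, so p-values measure the spread between those dissections. Each called list lost its call when camera estimated the correlation between genes from these 4 libraries. So did 5 of 5 planted lists of 30 genes with a 2-fold change in simulated counts. Simulated genes varied independently and most were unchanged, unlike the real ones. This therefore cannot tell whether the loss in the real lists came from low power or from shared variation.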

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

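The tests of explanations in this part were chosen after the result they bear on was seen. One of them, cup and comet against spermatid genes, is the stage order test fixed beforehand, and only its use here was chosen afterwards. Reads counted as ambiguous between genes lie outside the comparisons. They made up 3.513% and 3.528% of the total of gene and summary counts in the testis libraries and 1.574% and 1.664% in the seminal vesicle libraries. Alignments that were not unique made up a further 8.974% and 9.566% in testis and 8.27% and 8.415% in seminal vesicle. Genes that share exon bases with another gene on the same strand held 5.42% and 5.48% of gene counts in testis and 4.05% and 4.19% in seminal vesicle. Among named genes the largest such overlaps were those of vas (24.6% of exon bases), sgg (11.8%) and Syx1A (10.7%). Overlap on the opposite strand, as in Dark and Acp95EF, matters less if counting was strand-specific.

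Germline transcripts were present in both seminal vesicle libraries. Among 245 genes at 500 CPM or more in testis and over 2-fold higher there, the median level was 9.84% of the testis level in seminal vesicle replicate 1 (5th to 95th percentile 2.11% to 29.1%) and 21.8% in replicate 2 (5.06% to 41.6%). These genes were picked by their fold in the same libraries and not by germline identity. That choice leaves out genes with levels near those of testis and so limits the percentages. Carry-over of whole testis tissue as the only source would leave all stages at 1 share, but the mean log2 ratio of spermatid genes exceeded that of spermatocyte genes by 1.32 (two-sided permutation over genes, p = 0.0064). More remaining of transcripts made later would put cup and comet genes at or above spermatid genes, and their difference was -1.03 (permutation p = 0.014). Early germline genes stood at a median of 13.1% and 13.3% of the testis level, and they were in neither test. Carry-over of part of the testis, RNA in stored sperm and expression in the seminal vesicle itself stay open as untested, and so does a true difference between the tissues.

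Seminal vesicle replicate 2 stood above replicate 1 for testis-high genes. The median log2 ratio of replicate 2 over 1 was 1.05 for 2614 genes over 8-fold higher in testis (2.07-fold) and 0.02 for 2113 genes over 8-fold higher in seminal vesicle. A scaling difference between the libraries would move both sets alike, and their difference of 1.03 argues against it. A larger share of whole testis tissue in replicate 2 would raise all stages by like points of their testis level, but spermatid genes gained a median of 10.4 points (n = 40) and spermatocyte genes 1.85 points (n = 19), a difference of 8.59 points (two-sided permutation over genes, p = 0.00038). The median log2 ratio of replicate 2 over 1 was 1.14 for spermatid, 0.815 for spermatocyte, 1.33 for meiotic arrest, 1.39 for cup and comet and 1.23 for axonemal genes. Stages already differed in replicate 1, so a like ratio gives unequal points. The points test therefore repeats the stage difference above and is not separate evidence on replicate 2. Early germline genes, outside that test, had a median log2 ratio of replicate 2 over 1 of 0.17. A different cut between testis and seminal vesicle on the 2 days may have brought in more of the same material or another part of the testis. Neither was tested, and no group of the design gives a biological explanation.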

How the results depend on the processing

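The alternatives were fixed before the data were examined, except the fit without mitochondrial, rRNA and 2 dominant genes, chosen after seeing the data. Genes higher in seminal vesicle numbered 3342 to 5145 and genes higher in testis 4072 to 5922 over the alternatives, all within 1.5 times the reported counts. Of 134 named genes tested, 22 lost their call under at least 1 alternative, 7 gained one and 3 changed direction. The replicate block, on the inferred pairing by day, changed the call of no list or chromosome arm, and among named genes only those of SMC1, mle, Rpn6, Acp36DE and mt:lrRNA. The causes were not tested, except that leaving out a library leaves 1 in its tissue, which is then assumed to vary like the other tissue.

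With an estimated correlation, the adjusted p was 0.384 for muscle, basement membrane, humoral immunity, antioxidant, pigment, fat body and tracheal lists. It was 0.408 for early germline, testis proteasome, ejaculatory duct and water and solute transport lists, 0.423 for epithelial polarity, 0.437 for meiotic arrest and ER secretory lists, 0.44 for spermatocyte and cyst cell lists and 0.443 for the clock. It was 0.519 for axonemal, Y-linked, mitochondrial paralog and insulin lists, 0.531 for cup and comet and accessory gland lists, 0.54 for spermatid genes and 0.929 for the Y and chromosome 4. None of these calls was kept. In simulated counts, where genes varied independently and most were unchanged, that setting called 0 of 5 planted lists. The fry test gave adjusted p = 0.00789 for genital tract patterning, 0.0221 for the vacuolar ATPase, 0.0325 for neuronal and 0.0125 for dosage compensation genes.

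The sign of the median log2 fold change of a list or arm turned only where camera made no call. Camera compares a list with the other genes, so such a turn need not be one against them. For arm 2R the camera adjusted p was then 0.776 with DESeq2 size factors, 0.747 with library size only, 0.661 with spike-in factors, 0.786 with no filter and 0.868 with DESeq2. For dosage compensation it was 0.752 with library size only, 0.396 with spike-in factors and 0.912 with a filter of 5 CPM. For neuronal genes it was 0.667 with spike-in factors, 0.817 with no filter and 0.775 with DESeq2. The X median was -0.23 with spike-in factors (0.237), above the -0.97 of all genes. With a filter of 5 CPM the median turned for genital tract patterning (0.698) and for the vacuolar ATPase (0.798), whose camera direction was already positive. Leaving out each library in turn, it ran from 0.755 to 0.786 for 2R and from 0.704 to 0.971 for neuronal genes. The accessory gland list lost its call at 5 CPM (0.758) and with DESeq2 (0.12), and ranged from 0.000574 to 0.105 over left-out libraries. The stage order difference of spermatid minus early germline genes ranged from -1.24 to 0.16.

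Restricted genes numbered 227 for testis and 66 for seminal vesicle from 2 CPM up, 153 and 47 with 0 counts in the other tissue, and 199 and 131 on effective library sizes. Over left-out libraries they ran from 436 to 726 and from 140 to 215. Among named genes, the log2 fold change of Akt was -0.038 with library size only and -0.53 with spike-in factors, and with the latter Dark was at -0.25 and SMC1 at -0.35. Spike-in factors moved the median of all genes to -0.97, so those directions follow that shift. Depth limits genes near 0 counts, where a count of 0 allows 0.193 to 0.27 CPM.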

Other observations

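All tests in this part, on 20 gene families and on the hypotheses, were chosen after the data were seen. Cytosolic ribosomal protein genes were higher in seminal vesicle: of 87 tested, 78 were higher there and 8 higher in testis, at a median log2 fold change of 3.04 (camera adjusted p = 2.8e-10 over the 20 families; adjusted p = 0.546 with an estimated correlation). They took 6.17% and 4.83% of counts in seminal vesicle and 0.981% and 0.93% in testis. Of 70 mitochondrial ribosomal protein genes, 11 were higher in seminal vesicle and 23 higher in testis (camera adjusted p = 0.212). Of 67 cytochrome P450 genes, 54 were higher in seminal vesicle and 11 higher in testis (adjusted p = 5.06e-05; 0.481 with an estimated correlation), among them Cyp6d5 at 96.5 ± 17.2 against 1660.4 ± 623 CPM. The median log2 fold change of ribosomal protein genes was 2.18 with spike-in factors, and the named families kept their direction under each of the 4 scalings.

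Some other families were called and some not. Of 29 tetraspanin genes, 23 were higher in seminal vesicle and 5 higher in testis (camera adjusted p = 0.000593; 0.481 with an estimated correlation). All 6 Idgf genes of the chitinase-like family were higher there (camera adjusted p = 0.0124; 0.525 with an estimated correlation), with Idgf4 at 20.8 ± 1.02 against 3662 ± 170.2 CPM. All 4 scpr and Ag5r genes, of the cysteine-rich secretory protein family, were higher there (camera adjusted p = 0.0332; 0.546 with an estimated correlation), with scpr-C at 666 ± 69.4 against 7759.5 ± 145 CPM and scpr-A at 606 ± 54.1 against 6568 ± 0.446 CPM. Of 17 ionotropic receptor genes that passed the filter, 13 were higher in testis and 2 higher in seminal vesicle (camera adjusted p = 0.0332; 0.572 with an estimated correlation). Some had low levels and passed through testis alone, such as the testis-restricted Ir40a, Ir25a and Ir100a. Their testis means were 3.88, 3.45 and 2.72 CPM on total gene counts. Odorant-binding proteins (camera adjusted p = 0.0514), neprilysins (0.0775), ACX adenylate cyclases (0.212) and gustatory receptors (0.383) were not called, the last 2 with more genes higher in testis.

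A candidate explanation of the X-linked excess in seminal vesicle is a shift of all X-linked genes by about 1 factor. Among genes at 10 CPM or more in all libraries, the median log2 fold change was 0.64 for 652 X-linked genes and -0.03 for 3548 genes of the major autosomes. The difference was 0.666 (two-sided permutation over genes, p = 1e-05, the smallest these draws can give). The hypothesis came from these data. The difference does not show that every X-linked gene shifted alike, and fewer strongly testis-biased genes on the X stay open as untested.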
